A study of Sus scrofa with 10 samples.

How the data were processed

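RNA was measured on 10 Affymetrix Snowball arrays, a pig expression array, from alveolar macrophages of 5 Hampshire pigs. Per the labels' protocols, frozen cells were thawed and cultured overnight with recombinant human CSF-1. Non-adherent cells were then harvested and sorted by flow cytometry for large, granular cells. For labelling, 500 ng of total RNA was amplified and 5 µg of cDNA was fragmented and labelled, per the labels. The adherent arrays were taken over from an earlier series on the same individuals, per the series design. The labels call all samples untreated, at 0 h, although the protocol text of the adherent samples also describes removal of adherent cells and stimulation with lipopolysaccharide. Groups follow the cell type label, with 5 arrays each, and the animal number comes from the sample titles.

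The deposited values are log2 probe set values. The submitters' processing notes name RMA and Partek without a version or an order of steps. Whether both sets of arrays were normalized together is not given in the sources used here. Array medians lay between 4.97 and 5.09, and values ranged from 1.95 to 13.91. For arrays, the number of arrays limits the precision. Because the values were already on a log2 scale, no pseudocount was needed.

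Of 47845 probe sets, 26426 had 1 gene symbol in the platform annotation, 0 had several and 21419 were unnamed here, 123 of them array controls. The annotation can be old, and symbols are printed as it gives them. A gene was represented by its probe set with the highest mean over all 10 arrays, which gave 13755 genes, 6798 of them with more than 1 probe set. Among the genes past the threshold, 45 had another probe set past the threshold in the opposite direction.

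The comparison was non-adherent minus adherent, fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3 as 2-sided tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. All log2 differences are given in that direction, with the moderated standard error (SE). Every adjusted p for a gene comes from this fit unless another setting is named with it. The same fit was run over all probe sets, controls included. Gene lists were tested with limma's camera at its preset correlation of 0.01, for lists with at least 5 measured genes, adjusted over 36 lists. These held 1265 genes, of which 1006 were measured. All lists, the design and the main alternatives were fixed before the data were examined. Single values of the array controls were compared by an exact permutation test over all 252 arrangements. Figures were drawn with matplotlib 3.10.9.

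Genes are named by a fixed rule. The first part takes the 10 highest and 10 lowest log2 differences among genes past the threshold. These genes also had the same sign in all 5 animals and a mean in the higher group above the median of all probe sets, and locus and clone identifiers were left out. The second part takes up to 2 genes past the threshold per direction from each list, or the one with the lowest p where none passed. The third part always names CD163, CD14, SIGLEC1, MRC1, MARCO, ITGAM, PPARG and PTPRC. CSF1R, FCGR3A and CD68 also belonged to it and were not analysed here, since no named probe set carried those symbols.

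The same animals gave both groups, so the animal number pairs the arrays. Residuals of arrays with the same number correlated across genes at 0.116, 0.22, 0.398, 0.364 and 0.394 for animals 1 to 5, with a mean of 0.298 against -0.0715 for different numbers. Residuals cancel within each group, so a positive mean for the same number largely forces a negative one for different numbers. The contrast of these means is thus no separate support for the pairing. Genes are not independent replicates in these correlations. The fit with the animal as a block was an alternative. Adherent 1 correlated best with animal 2, and adherent 2 matched its own number only narrowly (0.22 against 0.203). No pair of arrays held identical values, and the animals are separate biological replicates.

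Other alternatives left out each animal and each array in turn, centred the arrays, applied quantile normalization, and kept only probe sets above the median level. Further ones used trended and robust variance, array weights, the mean of a gene's probe sets, a random animal effect, size thresholds (log2 of 1, and limma's treat at a fold of 1.5), estimated list correlations, fry, and lists without shared genes. Fry tests whether a list's genes change on balance in 1 direction and, unlike camera, does not compare them with other genes. After the data were seen, fits without control rows, with each array's high-GC background as a covariate, with the block but without animal 1, and with estimated list correlations without adherent animal 1 were added.

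The fit was tested on simulated data for this comparison, 13755 genes with 200 changed. It recovered 40.3% of genes changed by a log2 of 0.5, 82.1% at 1 and 98.5% at 2. Of 163 genes called, 5 had no simulated change (3.07%). A list of 30 genes shifted by 0.5 had an adjusted p of 3.69e-36, and 0 of the other lists passed. Simulated genes were independent, which real genes are not.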

Results

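Gene expression was measured in alveolar macrophages, the resident phagocytes of the airspaces, from 5 Hampshire pigs. From each pig, 1 array held cells that had stayed unattached after overnight culture (non-adherent, n = 5) and 1 held cells that had attached (adherent, n = 5). Non-adherent cells had been sorted for large size and high granularity, whereas no sort was stated for the adherent cells. The comparison asked how the expression of unattached macrophages differs from that of attached macrophages of the same animals. The adherent arrays came from an earlier series, so group and array series coincide. Differences between the groups therefore cannot be told apart from effects of the array series or of the sort. The 10 arrays covered 13755 named genes. Positive log2 differences mean higher expression in non-adherent cells, and errors are standard errors of the limma fit unless given as SD.

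Non-adherent cells had 2270 genes past an adjusted p of 0.05, of which 925 were higher and 1345 lower than in adherent cells. Of these, 327 differed by a log2 of at least 1, with 128 higher and 199 lower. The balance of directions depended on scaling and level. It was 752 higher and 1439 lower with centred arrays, and 1038 and 1169 after quantile normalization. Among genes with a mean log2 above 9, 315 were higher and 275 lower. Under the naming rule LAMP3, CCL22, AQP9 and C3AR1 had the largest rises, and CSF1, RNH1, CCL5 and PIM2 the largest falls. Over all 47845 probe sets, 5155 passed, 2264 higher and 2891 lower. The number of genes was 1119 without animal 3, 1445 without animal 4 and 1251 without animal 5. Without the array of adherent animal 1, which stood apart from the rest, 3067 genes passed, 2154 of them shared with the full set.

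LAMP3, a lysosomal membrane protein of maturing dendritic cells and alveolar type II cells, was 10.03-fold higher in non-adherent cells, with a mean log2 value of 8.32 ± 1.08 against 4.99 ± 0.23 (SD, n = 5 each). Its log2 difference was 3.33 ± 0.42 (adjusted p = 0.000623). CCL22, a chemokine for CCR4-bearing T cells, rose by 3.18 ± 0.32 (adjusted p = 0.000138). AQP9, a water and glycerol channel, rose by 3.18 ± 0.29 (adjusted p = 9.56e-05), and C3AR1, the receptor for complement C3a, by 3.06 ± 0.35 (adjusted p = 0.000319). STAT4, a transducer of interleukin-12 signals, rose by 2.89 ± 0.40. The protease ADAM19 rose by 2.72 ± 0.23, the calcineurin regulator RCAN1 by 2.67 ± 0.27, the transcription factor KLF7 by 2.61 ± 0.22 and heparanase, HPSE, by 2.45 ± 0.23. SLPI, a secreted protease inhibitor, rose by 2.73 ± 0.70 but varied between animals, with an SD of 1.80 in non-adherent cells. Its adjusted p of 0.0224 exceeded 0.05 when any of 4 arrays was left out (adherent 4 and non-adherent 1, 2 and 5), with a highest value of 0.0561. Leaving out both arrays of animal 1 (adjusted p = 0.0502), 2 (0.0792), 3 (0.0925) or 5 (0.0923) also ended the call of SLPI. Averaging all probe sets of a gene left the calls but gave smaller differences for AQP9 (1.62), C3AR1 (1.79), STAT4 (1.86), ADAM19 (1.40), KLF7 (1.32) and HPSE (1.18).

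CSF1, the macrophage growth factor, had the largest fall among the genes named by the rule, with a log2 difference of -2.48 ± 0.48 (adjusted p = 0.00579). RNH1, the ribonuclease inhibitor, fell by 2.36 ± 0.12 (adjusted p = 2.93e-06). CCL5, a chemokine for T cells and monocytes, fell by 2.30 ± 0.36, the kinase PIM2 by 2.17 ± 0.43 and EDN1, the precursor of the vasoconstrictor endothelin-1, by 2.16 ± 0.28. NDRG1, a gene induced by hypoxia, fell by 2.13 ± 0.15 (adjusted p = 2e-05). RENBP, the renin-binding protein, differed by -2.00 ± 0.10, and ACSS1, a mitochondrial acetyl-CoA synthetase, by -1.93 ± 0.15. The pseudokinase TRIB1 differed by -1.93 ± 0.30, and the potassium-chloride cotransporter SLC12A7 by -1.91 ± 0.20. All 20 of these genes differed in the same direction in 5 of 5 animals, which the naming rule required. With the mean of a gene's probe sets the calls stayed, at smaller differences for CSF1 (-1.51), RNH1 (-0.88), CCL5 (-0.61) and TRIB1 (-1.03).

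**Figure D1:**
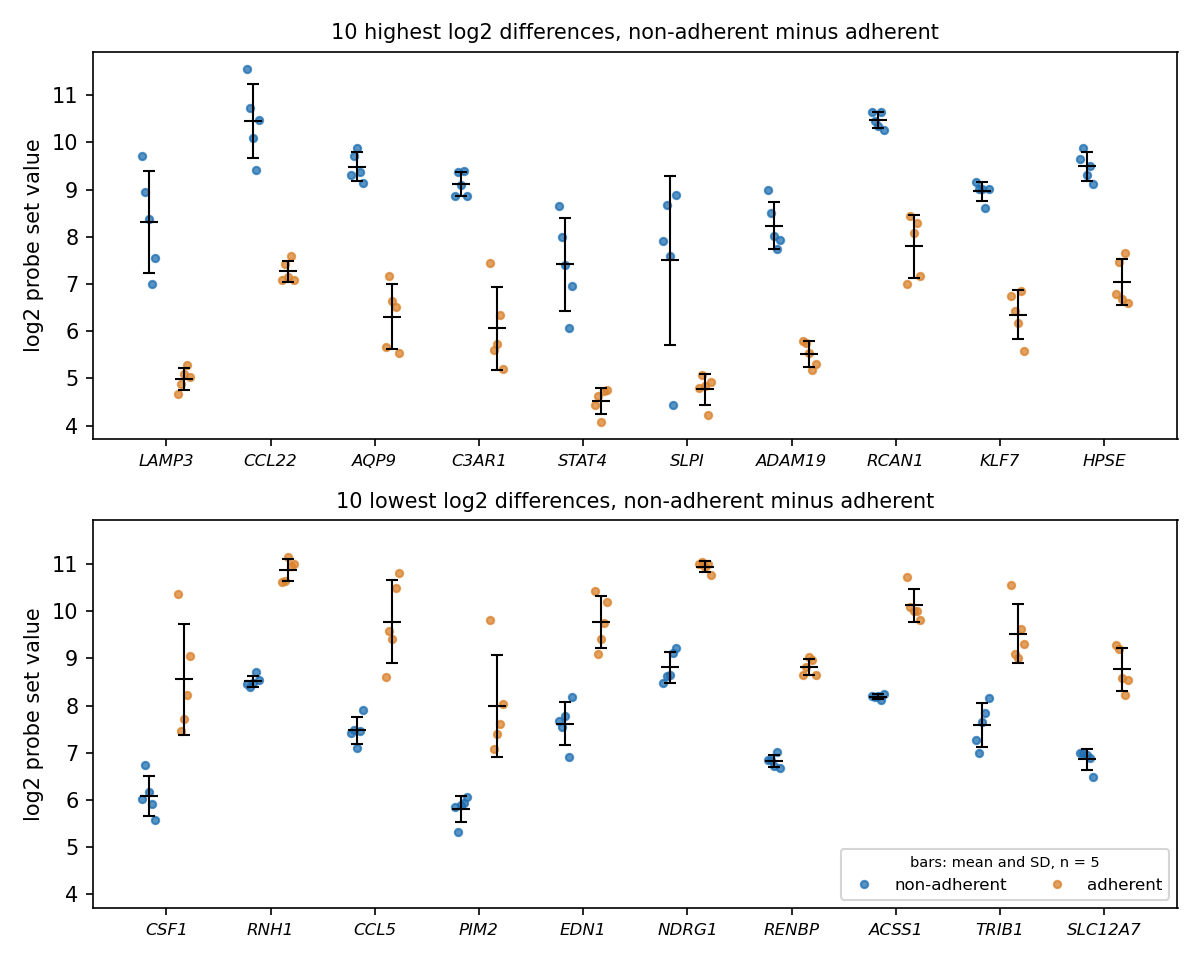
Log2 probe set values on each array for the 10 genes with the highest (top) and the 10 with the lowest (bottom) log2 difference under the naming rule, with the mean and SD of 5 arrays per group. SLPI varied widely between the non-adherent arrays (SD 1.80), whereas RENBP did not (SD 0.13).

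Dendritic cell markers were the only list that ranked higher in non-adherent cells by camera (adjusted p = 0.0441, and 0.969 with an estimated correlation). Of 25 measured genes, 7 rose, 3 fell and 15 did not pass, with 8 and 3 adjusted over the list alone. Besides LAMP3 and CCL22, CCL17 rose by 2.16 ± 0.28, FLT3, a growth factor receptor of dendritic cell precursors, by 1.91 ± 0.33, the lymph node homing receptor CCR7 by 1.83 ± 0.39 and the actin bundler FSCN1 by 1.78 ± 0.33. The call of CCR7 was lost without animal 3 (adjusted p = 0.0554). SIRPA, an inhibitory receptor of myeloid cells, fell by 1.09 ± 0.15, a call lost with the mean of its 2 probe sets (-0.33, adjusted p = 0.505). IRF8, a transcription factor of dendritic cell development, fell by 0.60 ± 0.17, a call lost when any of 7 arrays was left out (highest adjusted p 0.08) and with the animal as a block (0.0512). The list did not pass with the animal as a block (adjusted p = 0.0525), nor without adherent animal 2 (0.13), 3 (0.105) or 5 (0.0643), or non-adherent animal 2 (0.0585). It also did not pass above the median level (0.0515), after quantile normalization (0.0549) or without genes shared between lists (0.947). Fry, which tests for a change and not a rank among other genes, gave an adjusted p of 0.052.

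Genes of alveolar macrophage identity passed in both directions, and their list did not pass (adjusted p = 0.628). Of 27 measured genes, 2 rose and 6 fell, with 4 and 6 adjusted over the list alone, and 5 and 6 without adherent animal 1. CD163, the haemoglobin scavenger receptor, was 1.51 ± 0.44 higher (adjusted p = 0.0384) and higher in 4 of 5 animals. Without the array of adherent animal 1 the difference was 1.99 (adjusted p = 3.88e-05), and the call was lost when any of the other 9 arrays was left out, with a highest adjusted p of 0.0868. Leaving out both arrays of animal 2 (adjusted p = 0.137), 3 (0.139), 4 (0.13) or 5 (0.114) also ended the call of CD163. MSR1, a scavenger receptor, was 0.96 ± 0.26 higher, a call lost on leaving out any of 8 arrays (highest adjusted p 0.073). PPARG, a transcription factor needed for alveolar macrophages, fell by 0.64 ± 0.14, a call lost without animal 4 (adjusted p = 0.0513). APOE fell by 1.21 ± 0.26 and INHBA, a subunit of activin A, fell by 1.54 ± 0.32 (-0.48 with the mean of its probe sets). PTPRC, the leukocyte antigen CD45, rose by 0.79 ± 0.14. SIGLEC1 did not pass (1.15 ± 0.47, adjusted p = 0.12), although without adherent animal 1 its adjusted p was 0.00791, and 0.0148 with array weights. CD14 (0.44 ± 0.38), MRC1 (0.25 ± 0.20) and ITGAM (-0.18 ± 0.11) did not pass, although MRC1 passed with the mean of its probe sets (1.39, adjusted p = 0.00287). MARCO also did not pass (0.67 ± 0.22, adjusted p = 0.0579), and its adjusted p was 0.0461 without adherent animal 1 and 0.0492 among genes above the median level.

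Among scavenger, lectin and Fc receptors, 4 of 33 genes rose and 1 fell, with 5 and 2 adjusted over the list alone, and 2 and 2 with the animal as a block. FCGRT, the neonatal Fc receptor, fell by 0.67 ± 0.20, a call lost when any of 7 arrays was left out (highest adjusted p 0.0936). The list did not pass (adjusted p = 0.276). Without adherent animal 1, 12 rose, 1 fell and the adjusted p was 0.00057, or 0.377 with an estimated correlation. With array weights the list's adjusted p was 0.0235 at the preset correlation. In Toll-like receptor signalling, 6 of 31 genes rose and 5 fell, with 7 and 5 adjusted over the list alone (list adjusted p = 0.761). TLR7, an endosomal sensor of single-stranded RNA, rose by 2.34 ± 0.22 (adjusted p = 0.000101). TLR8, its close relative, rose by 2.15 ± 0.63, a call lost when any of 8 arrays was left out (highest adjusted p 0.0894), and by 0.92 with the mean of its probe sets. TOLLIP, an inhibitory adaptor, fell by 1.83 ± 0.15 and the peptidoglycan sensor NOD2 by 1.45 ± 0.30. For MHC class II and co-stimulation, 2 of 20 genes rose and 0 fell, with 1 and 0 adjusted over the list alone, and 2 and 1 with the animal as a block (list adjusted p = 0.24). The co-stimulatory ligand CD86 rose by 0.89 ± 0.18. CIITA, the MHC class II transactivator, rose by 0.74 ± 0.23, a call lost when any of 8 arrays was left out (highest adjusted p 0.107), and by 0.41 with the mean of its probe sets. Without adherent animal 1, 9 genes of this list rose, 2 fell and its adjusted p was 0.0121, or 0.617 with an estimated correlation. With array weights it was 0.0456 at the preset correlation.

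The lysosome list ranked lower in non-adherent cells (adjusted p = 0.000102, and 0.448 with an estimated correlation), with a median log2 difference of -0.32. Of 46 measured genes, 16 fell and 1 rose, with 22 and 1 adjusted over the list alone, and 22 and 2 without adherent animal 1. The sialidase NEU1 fell by 1.14 ± 0.19 and the protease CTSD by 1.11 ± 0.23, whereas the sulfatase IDS rose by 1.39 ± 0.15 (0.44 with the mean of its probe sets). Cholesterol biosynthesis also ranked lower (adjusted p = 0.000395, and 0.663 with an estimated correlation; median -0.65), with 7 of 18 genes lower and 0 higher, or 10 and 0 adjusted over the list alone, and 12 and 0 without adherent animal 1. INSIG1, which restrains sterol synthesis, fell by 1.48 ± 0.19 and ACAT2, an acetyl-CoA acetyltransferase, by 1.12 ± 0.19. In lipid uptake, storage and efflux, 13 of 48 genes fell and 5 rose, with 14 and 5 adjusted over the list alone. That list ranked lower (adjusted p = 0.0441), but its adjusted p was 0.155 without adherent animal 1, 0.121 without non-adherent animal 5, and 0.969 with an estimated correlation. It was 0.0533 without animal 5, 0.0619 with centred arrays, 0.0583 after quantile normalization, 0.28 above the median level, 0.0671 with array weights and 0.0516 with the mean of probe sets. The lipid droplet protein CIDEB rose by 1.94 ± 0.19 and the cholesterol exporter ABCG1 by 1.78 ± 0.41. The call of ABCG1 was lost without animal 2 (adjusted p = 0.0659), 3 (0.0712) or 5 (0.0615), and with the mean of its probe sets (0.75, adjusted p = 0.126). ACADVL, an enzyme of fatty acid oxidation, fell by 1.24 ± 0.11 (-0.56 with the mean of its probe sets). SCD, which desaturates fatty acids, fell by 1.27 ± 0.33, a call lost when any of 5 arrays was left out (highest adjusted p 0.0621).

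In the list of NF-kB feedback and immediate inflammatory targets, 10 of 34 genes fell, 1 rose and 23 did not pass, with the same counts adjusted over the list alone. The list ranked lower (adjusted p = 0.00371, and 0.969 with an estimated correlation), but did not pass above the median level (0.0515), and without adherent animal 1 it had 12 lower and 2 higher. NFKBIE, an inhibitor of NF-kB, fell by 1.64 ± 0.21 and the transcription factor IRF1 by 1.24 ± 0.20. TNIP3 rose by 0.81 ± 0.21, a call lost when any of 5 arrays was left out (highest adjusted p 0.0567) and with the mean of its probe sets (0.35, adjusted p = 0.244). Immediate early genes, the first to respond to a stimulus, ranked lower (adjusted p = 0.000564, and 0.969 with an estimated correlation; median -0.64), with 8 of 32 lower and 0 higher, or 9 and 0 adjusted over the list alone. DUSP1, a phosphatase of MAP kinases, fell by 1.55 ± 0.40, a call lost without non-adherent animal 1 or 2 (highest adjusted p 0.0548) and with the mean of its probe sets (-1.08, adjusted p = 0.0974). Leaving out both arrays of animal 3 (adjusted p = 0.0637), 4 (0.0787) or 5 (0.0566) also ended the call of DUSP1. Without adherent animal 1 this list had a median of -0.24, 12 genes lower and 3 higher (adjusted p = 0.0382, or 0.511 with an estimated correlation). Fry, a test of change alone, gave an adjusted p of 0.271 with all arrays. Of 39 inflammatory cytokines and chemokines, 7 fell and 1 rose, with 8 and 1 adjusted over the list alone, and 8 and 3 with the animal as a block (list adjusted p = 0.711). The protocol text of the adherent samples also describes stimulation with lipopolysaccharide, although the labels call them untreated at 0 h. Whether this bears on the inflammatory and immediate early lists was not tested. In the interferon response, 4 of 39 genes fell and 0 rose, with 1 and 0 adjusted over the list alone. With the animal as a block 2 fell and 7 rose, and without adherent animal 1, 7 fell and 0 rose. The interferon list's median of 0.08, its mean of 0.22 and its test pointed up (adjusted p = 0.761). TRIM25 fell by 0.87 ± 0.19, a call lost without animal 3 (adjusted p = 0.0661) or 5 (0.0553). LGALS3BP fell by 0.93 ± 0.28, a call lost when any of 7 arrays was left out (highest adjusted p 0.0985), after quantile normalization (0.0745) and with the mean of its probe sets (-0.57, adjusted p = 0.107).

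Integrins and adhesion receptors ranked lower (adjusted p = 0.0441, and 0.663 with an estimated correlation), with 8 of 34 genes lower and 0 higher, the same counts as when adjusted over the list alone. The counts were 7 and 1 with the animal as a block, and 10 and 2 without adherent animal 1. ITGA5, the fibronectin receptor subunit, fell by 1.57 ± 0.35 (-0.74 with the mean of its probe sets) and the tetraspanin CD81 fell by 1.44 ± 0.19. The list's adjusted p was 0.0853 without adherent animal 1, 0.0508 without adherent animal 3, 0.0509 without adherent animal 5, 0.0719 without non-adherent animal 3 and 0.0516 without non-adherent animal 4. It was 0.0777 without animal 3, 0.0502 without animal 5, 0.0501 with centred arrays and 0.0583 after quantile normalization. Above the median level it was 0.166, with array weights 0.0577, with the mean of probe sets 0.212 and without shared genes 0.0531. In focal adhesion and the actin cytoskeleton, 8 of 45 genes rose and 9 fell, with 9 and 12 adjusted over the list alone (list adjusted p = 0.761). Vinculin, VCL, rose by 1.32 ± 0.29, a call lost without animal 5 (adjusted p = 0.0614). Filamin A, FLNA, fell by 1.27 ± 0.20 (-0.52 with the mean of its probe sets) and the myosin heavy chain MYH9 by 1.27 ± 0.24. Of 24 genes of the extracellular matrix, 1 rose and 3 fell, over the list alone as well, and 2 rose and 3 fell without adherent animal 1 (list adjusted p = 0.761). Versican, VCAN, rose by 1.82 ± 0.40, a call lost without animal 3 (adjusted p = 0.0688) or 5 (0.0581). LAMB1 fell by 1.08 ± 0.17 (-0.66 with the mean of its probe sets). THBS2 fell by 0.68 ± 0.17, a call lost when any of 3 arrays was left out (highest adjusted p 0.0586) and with the mean of its probe sets (-0.43, adjusted p = 0.14). Of 26 matrix proteases and inhibitors, 3 rose and 0 fell, again over the list alone as well, and 4 and 3 without adherent animal 1 (list adjusted p = 0.761). Their median was -0.03, whereas their mean of 0.07 and the test pointed up. The plasminogen activator PLAU rose by 1.29 ± 0.32, a call lost when any of 3 arrays was left out (highest adjusted p 0.0517).

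Glycolysis and hypoxia genes ranked lower (adjusted p = 0.000564, and 0.969 with an estimated correlation), with 10 of 35 lower and 1 higher, and the same counts adjusted over the list alone. Without adherent animal 1, 13 fell and 1 rose, and the median moved from -0.225 to -0.368. The list's adjusted p was then 2.95e-06, or 0.536 with an estimated correlation. Besides NDRG1, VEGFA fell by 1.65 ± 0.14. The carbonic anhydrase CA9 rose by 0.51 ± 0.13, a call lost when any of 4 arrays was left out (highest adjusted p 0.063). The unfolded protein and amino acid stress list also ranked lower (adjusted p = 0.0133, and 0.969 with an estimated correlation), with 6 of 33 genes lower and 1 higher, or 8 and 1 adjusted over the list alone. The counts were 7 and 2 with the animal as a block, and 11 and 4 without adherent animal 1. EDEM1, which directs misfolded proteins to degradation, fell by 1.73 ± 0.17 and DDIT4, an inhibitor of mTOR, by 1.66 ± 0.27, whereas SEL1L rose by 0.86 ± 0.13 (0.35 with the mean of its probe sets). This list's adjusted p was 0.12 without adherent animal 1, 0.131 above the median level and 0.128 with array weights. Fry's test of change gave an adjusted p of 0.125 for this list and 0.0684 for glycolysis. Oxidative phosphorylation genes passed in both directions, with 8 of 42 higher and 6 lower, or 10 and 9 adjusted over the list alone (list adjusted p = 0.921). COX7C rose by 1.06 ± 0.13 and ATP5I by 0.92 ± 0.12, whereas SDHA fell by 1.07 ± 0.11 and NDUFB2 by 1.03 ± 0.09. For oxidative stress, haem and metals, 7 of 32 genes fell and 0 rose, also over the list alone, and the list did not pass (adjusted p = 0.26). Without adherent animal 1, 11 fell and 0 rose, and its adjusted p was 0.0377, or 0.536 with an estimated correlation. GPX4, which protects membranes from lipid peroxides, fell by 1.02 ± 0.11 and the mitochondrial superoxide dismutase SOD2 by 0.62 ± 0.14. The call of SOD2 was lost without animal 2 (adjusted p = 0.0631), 3 (0.0764) or 4 (0.054). Among p53 targets and apoptosis genes, 2 of 31 rose and 6 fell, with 2 and 8 adjusted over the list alone (list adjusted p = 0.648). The median was 0.02, whereas the mean of -0.13 and the test pointed down. BAX fell by 1.05 ± 0.14 and BAK1 by 0.88 ± 0.18, a call lost without animal 3 (adjusted p = 0.0561). CASP8 rose by 0.78 ± 0.16, a call lost with the mean of its probe sets (0.21, adjusted p = 0.217). PMAIP1 rose by 0.81 ± 0.20, a call lost when 1 array was left out (highest adjusted p 0.051). Of 19 heat shock genes, 0 passed, over the list alone as well, and 1 rose without adherent animal 1. FKBP4 had the lowest p (-0.52 ± 0.18, adjusted p = 0.0789). Of 57 ribosomal protein genes, 5 rose and 3 fell, over the list alone as well (list adjusted p = 0.616). Without adherent animal 1, 8 rose and 4 fell (adjusted p = 0.089, or 0.794 with an estimated correlation). Without both arrays of animal 1 the ribosomal list's adjusted p was 0.043 at the preset correlation, and 0.0504 with the block as well. RPLP2 rose by 0.70 ± 0.08. RPL19 rose by 1.43 ± 0.14, with 1 other of its 74 probe sets past the threshold, a call lost with their mean (0.18, adjusted p = 0.0517). RPL3 fell by 0.51 ± 0.10 and RPL35A by 0.50 ± 0.11, and the call of RPL35A was lost without animal 2 (adjusted p = 0.0552), 3 (0.0627) or 5 (0.0614).

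In cell cycle and DNA replication, 2 of 54 genes fell and 0 rose, over the list alone as well, and the list did not pass (adjusted p = 0.616). PCNA fell by 0.85 ± 0.21, a call lost with the mean of its probe sets (-0.46, adjusted p = 0.202) and without animal 3 (0.0633) or 5 (0.053). E2F1 fell by 0.80 ± 0.18, a call lost without animal 3 (adjusted p = 0.0742). On the array of adherent animal 1 the genes of the list lay at a median of 1.41 above the other adherent arrays. Without that array, 25 genes rose and 2 fell. The list then ranked higher in non-adherent cells at the preset correlation (adjusted p = 2.95e-06) but not with an estimated correlation (adjusted p = 0.511). With array weights its adjusted p was 0.00156 at the preset correlation.

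**Figure D2:**
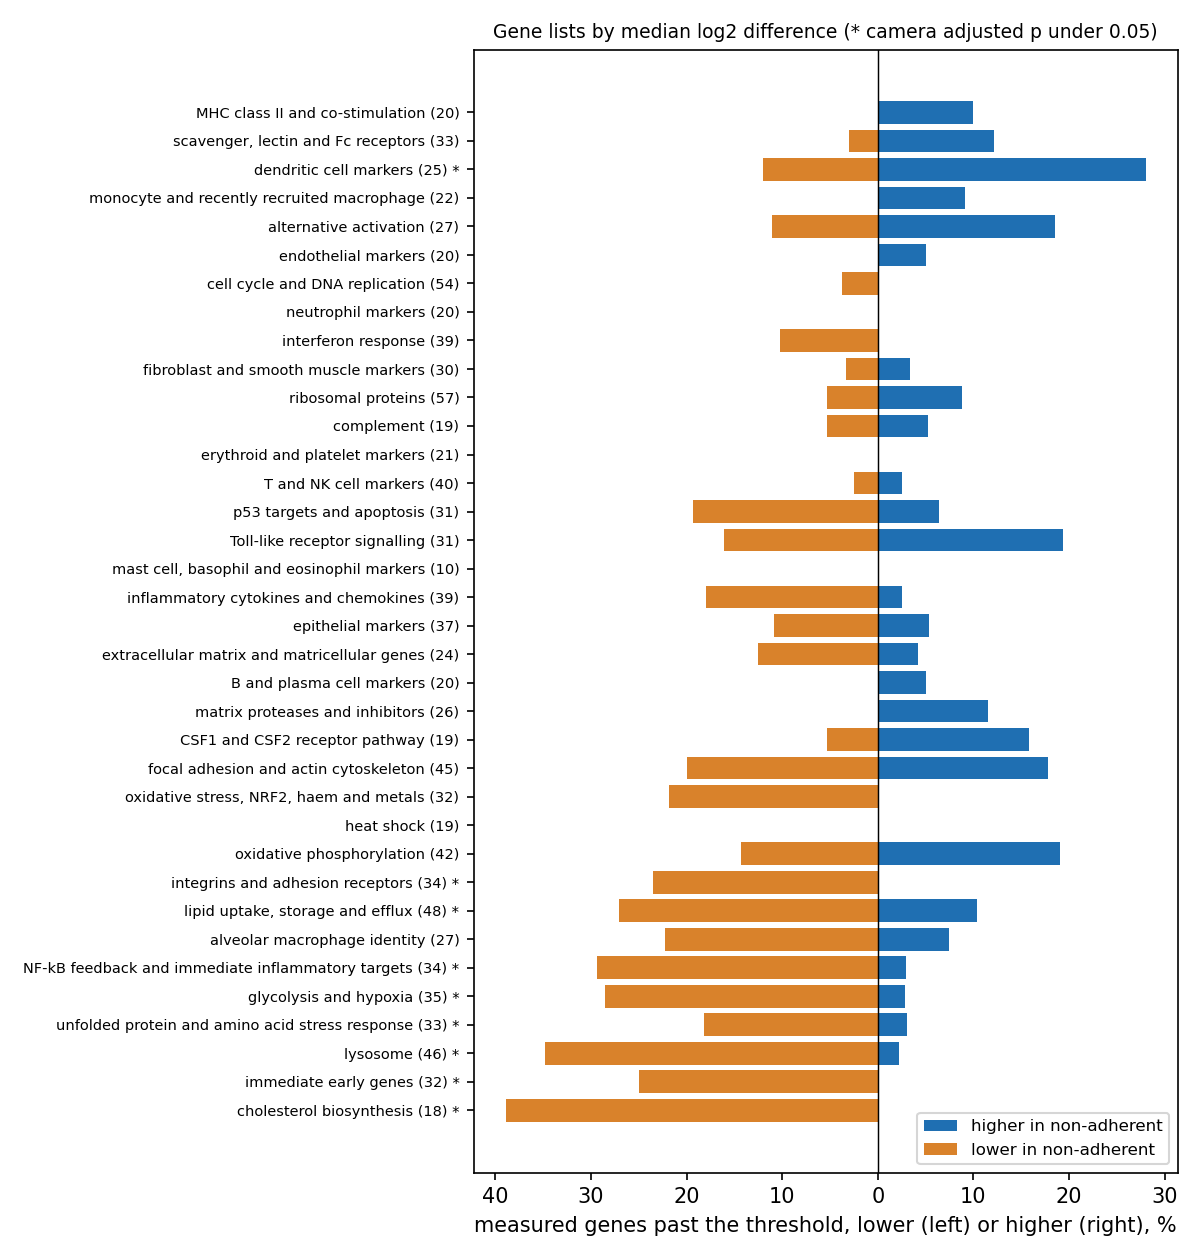
Percent of the measured genes of each of the 36 lists that were past the threshold and higher (right) or lower (left) in non-adherent cells, with the number measured in parentheses. Lists are ordered by median log2 difference, from -0.65 for cholesterol biosynthesis at the bottom, and an asterisk marks the 9 lists with an adjusted p under 0.05 at the preset correlation.

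Alternative activation had 5 of 27 genes higher and 3 lower, with 5 and 5 adjusted over the list alone and with the animal as a block (list adjusted p = 0.599). Arginase 2, ARG2, fell by 1.71 ± 0.32. The chemokine CCL24 fell by 0.95 ± 0.26, a call lost when any of 5 arrays was left out (highest adjusted p 0.0679). In the CSF1 and CSF2 receptor pathway, 3 of 19 genes rose and 1, CSF1, fell, over the list alone as well (list adjusted p = 0.921). Its median of -0.05 and mean of -0.02 differed in sign from the test, which pointed up. The counts were 3 and 3 with the animal as a block, and 5 and 2 without adherent animal 1. Among monocyte genes, 2 of 22 rose and 0 fell, with 1 and 0 adjusted over the list alone or with the animal as a block, and 4 and 2 without adherent animal 1 (list adjusted p = 0.711). The chemokine receptor CCR2 rose by 0.77 ± 0.23, a call lost with the animal as a block (adjusted p = 0.0559), with centred arrays (0.0555), after quantile normalization (0.0655) and when any of 7 arrays was left out (highest 0.0984). Of 19 complement genes, C3AR1 rose and C2, which fell by 1.06 ± 0.19, was the other of 2 that passed, over the list alone as well (list adjusted p = 0.689), and without adherent animal 1, 3 rose and 1 fell.

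None of 20 neutrophil, 10 mast cell and granulocyte, or 21 erythroid and platelet genes passed, over each list alone as well. The lowest p values there belonged to VNN2 (0.88 ± 0.30, adjusted p = 0.0663), ENPP3 (0.29 ± 0.12, adjusted p = 0.132) and GP1BA (0.23 ± 0.09, adjusted p = 0.093). Without adherent animal 1, ENPP3 passed (adjusted p = 0.0496), as did 1 neutrophil gene, and VNN2 passed with array weights (0.0225). Of 40 T and NK cell genes, CCR7 rose and LAT fell by 0.58 ± 0.08, over the list alone as well. The T and NK counts were 2 and 2 with the animal as a block, and 3 and 3 without adherent animal 1. Of 20 B and plasma cell genes 1 rose, FCRLA (0.38 ± 0.12), and of 20 endothelial genes 1 rose, TEK (0.58 ± 0.16), with 0 in either list adjusted over the list alone. With the animal as a block 2 rose in each, and without adherent animal 1, 2 rose and 2 fell for B cells and 3 rose for endothelial cells. Among 30 fibroblast and smooth muscle genes, COL1A2 rose by 0.33 ± 0.09 and PDPN fell by 0.64 ± 0.20, with 0 adjusted over the list alone, and COL1A2 did not pass with the animal as a block (adjusted p = 0.0641), where 0 rose and 2 fell. The calls of FCRLA, TEK, COL1A2 and PDPN were each lost when any of 7 or 8 arrays was left out. With the mean of probe sets FCRLA (0.15, adjusted p = 0.113) and PDPN (-0.31, adjusted p = 0.116) were lost, as they were with centred arrays (0.0556 and 0.0508), and PDPN also after quantile normalization (0.0645). Of 37 epithelial genes, 2 rose, LAMP3 and SLPI, and 4 fell, with the same counts over the list alone. EPCAM fell by 1.35 ± 0.32, a call lost without animal 3 (adjusted p = 0.0678) or 4 (0.0521). ABCA3 fell by 0.89 ± 0.25, a call lost when any of 6 arrays was left out (highest adjusted p 0.0795) and with the mean of its probe sets (-0.28, adjusted p = 0.215). Median and test differed in sign for B and plasma cells (-0.03, up) and epithelial genes (-0.01, up), and the mean did for fibroblast genes (-0.03, with a median of 0.06 and the test up). The lists' adjusted p values ran from 0.357 (endothelial) to 0.944 (epithelial, and mast cell and granulocyte).

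**Figure D3:**
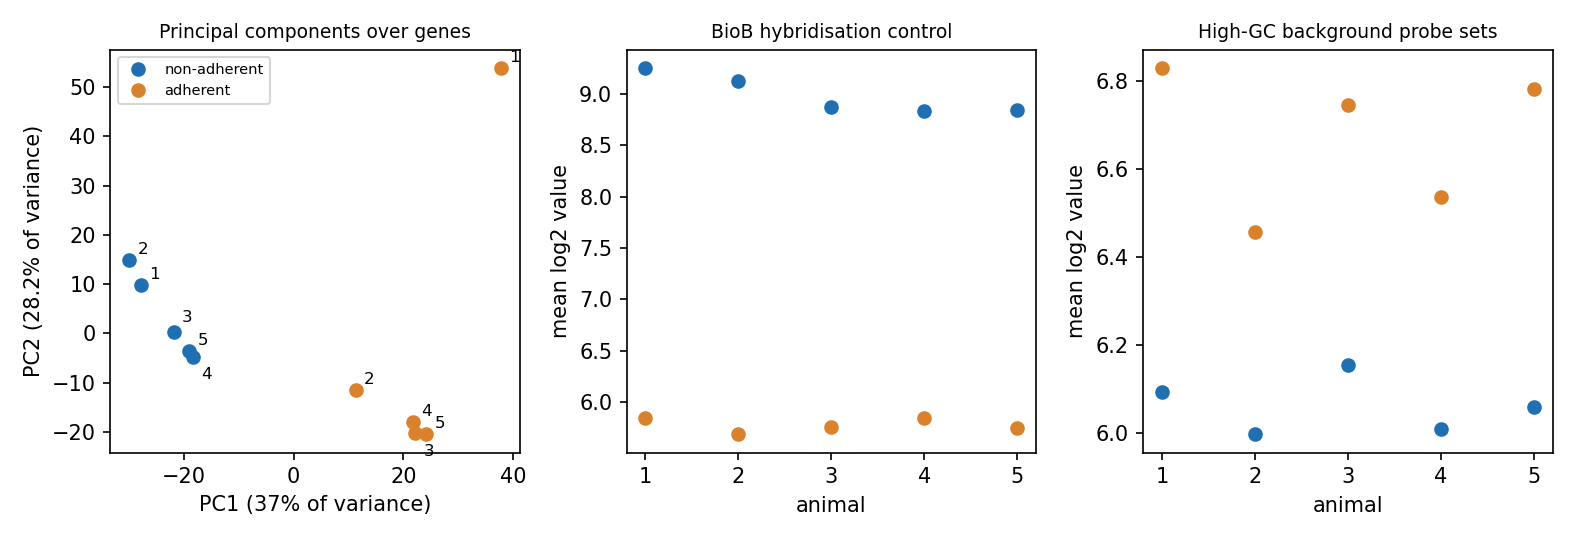
Left, the first 2 principal components over genes (37% and 28.2% of the variance), with animal numbers; middle and right, mean log2 value of the BioB hybridisation control and of the high-GC background probe sets by animal, with non-adherent arrays in blue and adherent arrays in orange. Both control measures shown separate the groups, at 8.98 against 5.78 for BioB, and adherent animal 1 lies apart on the second component at 53.8.

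Array series and group coincide in this design, and 3 of 5 measures of control probe sets differed between the groups. BioB and CreX, spiked hybridisation controls that hold no sample RNA, were 3.2 and 0.271 higher on non-adherent arrays. The high-GC background differed by -0.607. Group and array series therefore cannot be told apart. The low-GC background (-0.0167, exact permutation p = 0.46) and the poly-A spikes (-0.0192, exact permutation p = 0.96) did not pass. The 9 lists at the preset correlation were not more than other groupings gave, since 41 of 100 splits of the arrays had at least as many, and 0 lists passed with an estimated correlation (2 of 36 at an unadjusted p under 0.05).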

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

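The tests of the background slope over all genes and both slopes without adherent animal 1 were chosen only after those results were seen. So were the tests of the BioB control, the poly-A spikes and the immediate early genes. The additive background bound, the slope of the 3 lists on all 10 arrays and the splits of the arrays were chosen before. Those 3 lists are among the 8 that ranked lower in these data, and the other lower lists were not put to the slope test. Of 228 groups of 5 arrays tested for an array far from the others, 19 stood out (8.33%, against about 1 in 20 by chance), 12 of them with adherent animal 1.

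Adherent animal 1 lay apart on the second principal component (gap 0.879 of the group's range) and in its mean correlation with its own group (gap 0.959, at a correlation of 0.9523). The same array was high for CD81 (0.784), MYH9 (0.729), CTSD (0.785), INSIG1 (0.729), FCGRT (0.793), CCR7 (0.729), IRF8 (0.72) and TEK (0.871), and low for SOD2 (0.748) and EDEM1 (0.803). Its poly-A spikes, added in a fixed amount, were 7.289 against 5.593 to 6.796 on the other 9 arrays, as less sample RNA would give. This is weak evidence, since the other adherent arrays already ran from 5.593 to 6.677. The test for an array far from the others did not flag these spikes. The immediate early genes of adherent animal 1 lay 1.7 above the other adherent arrays, as a stimulated culture would give. These 2 explanations do not exclude each other. The shift was not particular to immediate early genes. Cell cycle (median 1.41) and monocyte genes (1.02) also lay above the other adherent arrays, and glycolysis (-0.606) and oxidative stress genes (-0.47) below them. Other explanations were not tested.

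Other arrays stood apart from their group for single genes, no more often than the 5% expected by chance over the 228 groups tested. These were KLF7 (0.718, low on non-adherent animal 4), PIM2 (0.727, low on non-adherent 2), SLC12A7 (0.786, low on non-adherent 5), FCGRT (0.739, low on non-adherent 5), GPX4 (0.787, low on non-adherent 2), LAT (0.725, low on non-adherent 2) and RPL35A (0.879, low on adherent 4).

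Of 5 array control measures, which the comparison of genes does not use, 3 differed between the groups. BioB was 3.2 higher, CreX 0.271 higher and the high-GC background -0.607 on non-adherent arrays (exact permutation p = 0.00794 each, the smallest that 252 arrangements allow). The low-GC background (-0.0167, exact permutation p = 0.46) and the poly-A spikes (-0.0192, exact permutation p = 0.96) did not pass. For lower genes above a log2 of 9, an additive background on the adherent arrays could add a log2 of at most 0.48. Of these 275 genes, 96.4% fell by more than it can add, by over 1 SE. This argues against it as the whole cause for most of them, and does not measure its part in the fall. These genes had been selected as lower at the threshold, which favours a fall above the bound. The dimmer genes among the 1345 lower ones were not tested. For those dimmer genes an additive background is not excluded. An array effect that runs with the background stays open: the slope within groups had a Spearman rho of -0.233 with the difference (permutation p = 0.0891), and -0.246 (0.0495) without adherent animal 1. For lysosome, cholesterol and glycolysis genes the slope predicted -55.3% of the difference (SD 68.3), below the bound of 25% set in advance against this explanation by more than 1 SD. That value rested on 1 array, since without adherent animal 1 it was 37.1% (SD 22.9). The median slope of these lists lay at percentile 4.1 among random lists matched on level with all arrays. Without adherent animal 1 it lay at percentile 100, the side that an array effect calls for. The explanation is therefore not excluded for these lists. A batch other than background (BioB, 3.2) cannot be told apart from attachment or the sort for size and granularity, both untested, because every array of a group comes from 1 series.

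For genes, 1 of 100 splits drawn from 126, the real one, gave as many calls (2270 against at most 1). For probe sets it was also 1 of 100 (5155 against at most 1). In the fit without a block, other splits thus did not give these counts. They leave the pairing by animal aside and all mix the array series, so they cannot part group from series. For gene lists chance is not excluded, since 41 of 100 splits gave at least the 9 of the real one, with a highest count of 19. With the animal as a block, 1 of 16 splits gave as many genes (2506 against at most 26), and 16 splits are too few for a share under 0.05.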

How the results depend on the processing

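The fit with the high-GC background as a covariate, the fit without control probe sets, the block without animal 1 and the estimated correlation without adherent animal 1 were chosen only after the results were seen. Over each animal and array left out, genes past the threshold ranged from 1119 to 3067 (higher 387 to 1285, lower 732 to 1782), probe sets from 2289 to 6511 (higher 846 to 2854, lower 1443 to 3657) and lists from 6 to 11. The block gave 2506 genes, 2005 of them shared, and among named genes and lists changed no call other than those given with the results. The mean of a gene's probe sets gave 2159 genes and 7 lists; of 95 named calls it ended 12 and moved 19 others by over 1.5 times, and it added MRC1. With a log2 of at least 1 there were 327 genes (128 higher, 199 lower) and 800 probe sets (322, 478), and with a tested fold of 1.5 there were 92 (28, 64) and 168 (59, 109), fewer because the threshold is stricter. Lists numbered 4 above the median level, 0 with estimated correlation (0 also without adherent animal 1) and 5 with fry, which tests for change and not against other genes, and the cause was not tested. The block without animal 1 gave 3495 genes, 1584 of them higher, and the cause was not tested. With the covariate, 4 genes passed (0 higher, 4 lower) and 12 probe sets (3, 9). The covariate correlates with the group at -0.939 and widened the named genes' standard errors by a median of 2.91 times, which ended the call of LAMP3 at a similar difference (3.33 ± 0.424 before, 3.44 ± 1.29 after), whereas for AQP9 the difference shrank as well (3.18 ± 0.294 before, 1.45 ± 0.685 after). Of the named genes past the threshold, 1 kept its call, RENBP. Among named calls, only under it did signs turn, for CSF1 (0.129), PIM2 (0.441), FLNA (0.0266), PCNA (0.341), CD86 (-0.017), FCGRT (0.205), DDIT4 (0.0917), DUSP1 (0.336), IRF8 (0.366) and ABCA3 (0.227), and the list tests turned for NF-kB feedback (median -0.0991), unfolded protein (0.402) and immediate early genes (0.832). These 3 lists did not pass under it, nor did cholesterol biosynthesis (-0.43, adjusted p = 0.0964), integrins (0.865) and lipid uptake (0.516), while lysosome, glycolysis and dendritic lists kept their call. Monocyte (1.07), cell cycle (1.27), alternative activation (0.614), scavenger (0.619) and oxidative stress lists (-0.711) passed at the preset correlation, and heat shock turned and passed (0.202), and also had a positive median without adherent animal 1 (0.0152), without animal 1 (0.0286) and with array weights. The cause was not tested. Of 95 named genes past the threshold, 73 kept their call without any 1 array and 61 also without any 1 animal. Where the results give a gene's highest adjusted p over single arrays left out, leaving out both arrays of an animal gave a higher one. The number of arrays limits precision, and a pseudocount was not run, since the values are log2.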

Other observations

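The carry-over test and both dendritic cell lists of this part were chosen only after the dendritic cell results were seen. Of 17 measured genes of dendritic cell maturation, 6 rose in non-adherent cells and 1 fell, with a median log2 difference of 0.18. Of 13 measured lineage genes of conventional dendritic cells, 2 rose and 2 fell (15.4% higher), with a median of 0.17.

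Dendritic cells carried over into the sorted fraction are a possible explanation for the higher maturation genes. Of the 8 lineage genes above the median of all probe sets, 2 rose (25%) and 2 fell. FLT3 (1.91) and XCR1 (0.865, adjusted p = 0.0435) rose, whereas IRF8 (-0.60) and WDFY4 (-0.44) fell by less. The share of 25% lay between the 50% set for carry-over and the 20% set against it, so the test decides nothing. The restriction to those 8 genes was set after the count over all 13 (15.4%) had been seen, and that count would have met the bound against carry-over. The restriction was made because genes near the floor exclude nothing. The sort gate, which could have enriched large granular cells of either kind, was not tested.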
